A study of Caenorhabditis elegans with 5 samples.

How the data were processed

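The series measured polyadenylated RNA of whole worms of the wild-type Caenorhabditis elegans strain N2 at 5 developmental stages, the larval stages L1, L2, L3 and L4 and the adult. Each stage has 1 deposited sample. Per the labels, the L1, L2 and L4 samples each stand for 2 hybridizations and the L3 and adult samples for 3. Per the submitters' layout note, 6 two-colour arrays were hybridized, each with 1 stage in Cy3 and another in Cy5, and every stage was labelled with both dyes on different arrays. Per the labels' protocols, RNA was purified in Trizol, enriched in 2 rounds for polyadenylated RNA and reverse transcribed with random nonamers and an anchored oligo-dT primer into aminoallyl cDNA that was coupled to Cy3 or Cy5. Agilent Feature Extraction 9.5 is named in the submitters' processing notes. How the dye channels and hybridizations were combined, and how the values were normalized, are not given in the sources used here.

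The deposited values form 1 table of 240997 probes and 5 columns, all 5 of which were mapped to a stage by the sample accession. The authors' values are a score on a log-like scale whose base is not given. They ran from -1.68 to 8.97. The L2 column ended in a ceiling at 8.54 and the L4 column at 8.37, with 1700 and 704 probes within 0.01 units of the top. The distance from the 5th percentile of L2 to its ceiling was 6.22 units, which is 74.4-fold if the base is 2 and 502-fold if it is natural. These readings were not told apart, so differences are given in units of the deposited scale and not as folds. A difference of 1 unit is 2-fold on a base-2 scale and 2.72-fold on a natural one. Signal over background could not be assessed, since the table holds no background measure, and low values have no known floor.

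Probe identifiers consist of a prefix (CAS, RRM, EXP1, EXP2 or GENE) and a number. The meaning of the prefixes is not given in the sources used here, and 0 of the 240997 identifiers matched a gene identifier, symbol, synonym or accession of the gene table that was used (assembly WBcel235). No probe could therefore be named by gene. The planned gene lists, and the planned naming of genes, were not applied. The probe took the place of the gene as the unit of comparison. The named items are at most 2 identifiers that were higher and 2 that were lower in each comparison, those with the largest change among the CAS probes, because these carry an error over spots.

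The rule fixed before the data were examined was to use the deposited scale only if the 5 column medians lay within 0.1 units and the interquartile ranges within 10% of each other. The medians spanned 0.21 units and the largest interquartile range was 1.33 times the smallest, so the columns were quantile normalized. The deposited values and columns centred on their medians are alternatives. A probe was kept if its highest value over the 5 stages reached the pooled median of all values (5.00 units), which left 164049 probes. A probe was counted in a comparison when its 2 stage values differed by at least 1 unit. With 1 sample per stage there is no replicate check, no test across samples and no p-value. The design assumed log2 values per gene, and the move to probes and to units of the deposited scale was made after the files were seen.

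The CAS class has 11976 identifiers, which equals 4 times 2994. Per the series' design text, 499 cassette events were profiled with 3 exon and 3 junction probes each, that is 6 probes per event. CAS identifiers 2994 numbers apart had mean levels that correlated at r = 0.977. Among the distances up to 9000 that are not multiples of 2994 the highest correlation was 0.407. They were therefore treated as 4 spots of 1 probe, giving 2994 sets, which is an inference from the values. A set was named by its lowest number. Sets with close numbers may be probes of 1 event, so 2 named sets are not always separate changes. Class counts and shares of CAS probes count each identifier, so 1 probe can enter 4 times. A set was counted when its mean change reached 1 unit and all 4 spots changed in the same direction. The SD over the 4 spots measures spot error within these arrays and not the spread between worm cultures. Counts from spot error alone came from 100 draws in which the spot residuals of each set were given random signs. On simulated data with 2027 sets, the counting rule called 100 of 100 sets that differed by 1.5 units, 5 of 100 that differed by 0.75 units, below the threshold, and 0 of 1827 unchanged sets. The simulation used a spot SD of 0.22 units. It does not cover probes with a larger spot SD or differences between worm cultures.

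The RRM and EXP1 class medians were set against 10000 random lists of the same number of probes, matched on mean level in 10 bins. The CAS, EXP2 and GENE medians were not set against such lists. Probes of a class can share a transcript, so the random lists vary less than lists of independent genes would, and the percentile is only a description of these samples. Correlations between stages are across probes, which are not independent replicates. The alternatives were the deposited values, median centring, no level filter, a 75th percentile filter and a threshold of 2 units. A threshold of 0.69 units and the removal of probes at a ceiling were added after seeing the data. A mean over the probes of a gene and a floor for linear values, both planned, did not apply. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.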

Results

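To follow transcript and exon signals through postembryonic development, wild-type worms were profiled at the 4 larval stages, L1 to L4, and as adults, with 1 deposited sample per stage. C. elegans passes through these larval stages, each closed by a moult, before it becomes a fertile adult. The array held 240997 reported probes, of which 187619 carried the prefix GENE, 38581 EXP2, 11976 CAS, 1671 EXP1 and 1150 RRM. No gene name accompanies the probes, so the results describe stages and probe classes. The number of arrays, 6 in all with 2 stages on each, limits the precision, and no value between stages has a replicate of the worms behind it. The only error that can be given is that between the 4 spots of a CAS probe. Its median SD was 0.27 units in L1, 0.21 in L2, 0.22 in L3, 0.25 in L4 and 0.18 in the adult. Spot SD was smaller for brighter probes, with a median of 0.35 units below a level of 3 and 0.10 at 8 or more.

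L2 and L3 were the closest pair of stages. Over the 164049 probes that passed the level filter, Pearson's r was 0.91 for L2 and L3, 0.76 for L1 and L2, 0.74 for L3 and L4 and 0.72 for L4 and the adult (Spearman's rho 0.89, 0.75, 0.76 and 0.71). L1 and L3, which are not adjacent, had an r of 0.709, and as deposited their r of 0.713 lay above the 0.710 of L4 and the adult. The lowest r, 0.37 (rho 0.37), was that of L1 and the adult. The adult correlated with L3 at 0.53 and with L2 at 0.48, although the adult and L2 were hybridized together on 2 arrays. Without the level filter r was 0.945 for L2 and L3, 0.874 for L3 and L4, 0.873 for L1 and L2 and 0.861 for L4 and the adult, so that L2 and L3 stayed the closest pair and the other adjacent pairs lay close together.

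From L1 to L2, 18419 probes were higher and 14469 lower in L2 by at least 1 unit, together 20.05% of those kept. The EXP1 class had the largest share of such probes, 31.8%, against 22.8% of EXP2, 19.5% of GENE, 18.5% of CAS and 15.3% of RRM. At 2 units or more the counts were 2537 higher and 2036 lower. Among the CAS sets, 162 were higher and 128 lower in L2 (234 and 66 as deposited, 185 and 96 after median centring), while spot error alone gave at most 1. CAS:2100 went from 5.30 ± 0.14 in L1 to 7.98 ± 0.05 in L2 (SD, n = 4 spots), a change of 2.68 ± 0.10 units. CAS:2099, the neighbouring number, was 2.68 ± 0.26 units higher and may be a probe of the same event. CAS:3271 lay at 8.36 ± 0.12 in L1 and 4.01 ± 0.30 in L2, a change of -4.34 ± 0.34, and CAS:3272 changed by -3.71 ± 0.13. The split by direction depended on the scaling: 56.0% of the probes counted were higher in L2 after quantile normalization and 70.6% in the deposited values, where the median kept probe was 0.17 units higher in L2.

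L2 and L3 differed least of all adjacent stages. Only 5.66% of the kept probes differed by 1 unit or more, 4514 of them higher and 4772 lower in L3. At 2 units, 167 were higher and 103 lower. The CAS class leaned to lower values in L3, with 1.32% of its probes higher and 3.95% lower. Its median change relative to all kept probes was -0.14 units, and it was -0.15 in the deposited values. In the sets of 4 spots, 9 were higher and 44 lower. CAS:2272 was 1.46 ± 0.27 and CAS:824 1.37 ± 0.37 units higher in L3. CAS:2114 changed by -1.90 ± 0.29 and CAS:2108 by -1.76 ± 0.34. Of the RRM probes, 32 were higher and 9 lower, and their median change of 0.023 units lay within the central 95% of 10000 level-matched random lists of probes. EXP1 had 100 probes higher and 30 lower (98 and 48 as deposited). The EXP1 median change of 0.12 units lay above the highest of its random lists (0.065). Relative to all kept probes the EXP1 median was 0.10 units but 0.013 as deposited, so no direction is given for it.

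Most of the differences of at least 2 units between L3 and L4 went to higher levels in L4. At 1 unit the counts were 13603 higher and 11680 lower, but at 2 units 4451 probes were higher and 578 lower, and at 0.69 units the order turned, with 23602 higher and 25261 lower. In the deposited values the counts at 2 units were 4740 and 347. Of the kept probes of each class, 10.3% of EXP1, 6.06% of EXP2, 5.74% of RRM, 2.06% of GENE and 1.32% of CAS were at least 2 units higher in L4; in number, GENE held 2630 of them, EXP2 1509 and EXP1 135. The 4451 probes had median levels of 3.19 in L1, 2.95 in L2, 3.09 in L3, 6.06 in L4 and 5.25 in the adult. In the adult, 62.0% of them were still at least 2 units above their L3 level, and 34.9% were at least 1 unit below their L4 level, against 11.4% of all kept probes. Part of that fall can come with the choice of probes by a high value in 1 L4 sample. The choice also favours low values in 1 L3 sample, which can raise the 62.0%. That share has no value for all kept probes beside it, and neither part was measured. CAS:1609 showed this course with 1.62 ± 0.28 in L3, 6.87 ± 0.35 in L4 and 5.41 ± 0.18 in the adult, and CAS:1612 with 1.72 ± 0.24, 6.87 ± 0.44 and 5.59 ± 0.09. Their changes from L3 to L4 were 5.25 ± 0.52 and 5.15 ± 0.49 units. In the other direction, CAS:1847 changed by -2.2 ± 0.25 and CAS:1845 by -2.07 ± 0.24. Over all CAS sets, 90 were higher and 87 lower in L4 (95 and 48 as deposited, 88 and 65 after median centring), with at most 1 from spot error. The scaling moved the split at 1 unit, with 53.8% of the probes higher in L4 after quantile normalization and 65.2% as deposited. The median RRM change was 0.056 units, just above the highest of 10000 level-matched random lists (0.055). Relative to all kept probes it was 0.10 units, also 0.10 as deposited.

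**Figure D1:**
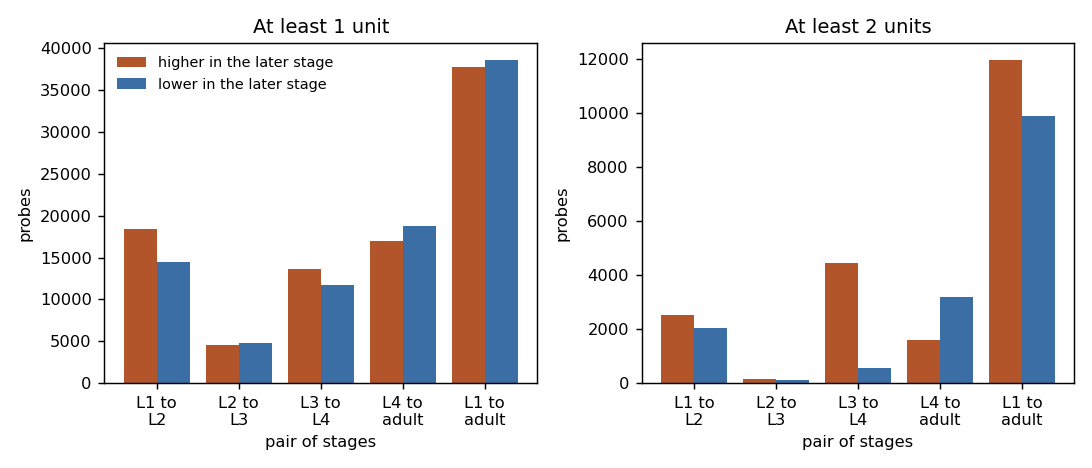
Bars give the number of probes (vertical axis) that were higher or lower in the later stage of each pair (horizontal axis), by at least 1 unit (left) or 2 units (right) of quantile-normalized signal, among 164049 kept probes, with 1 sample per stage and no error bars. L2 to L3 has the fewest, and at 2 units L3 to L4 has 4451 higher against 578 lower probes.

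The step from L4 to the adult had the most differences of at least 1 unit among adjacent stages. In the adult 16934 probes were higher and 18763 lower, or 21.8% of those kept. The order turned in all probes without a level filter (24403 and 23805). Among adjacent pairs only L3 and L4 shared an array, so differences between arrays may enter the counts of the steps unequally. At 2 units the order of the directions was the opposite of that from L3 to L4, with 1614 higher and 3178 lower, in all 4792 against the 5029 from L3 to L4 (5963 against 5087 as deposited and 6706 against 4749 after median centring, so that the larger of the steps at 2 units depends on the scaling). The deposited values gave 2243 higher and 3720 lower, but median centring turned the order of the directions, with 3872 higher and 2834 lower. The EXP2 class had 1908 probes higher and 4100 lower at 1 unit (3835 and 3339 after median centring, which flips the direction), and EXP1 had 91 and 255 (154 and 204). The RRM class had 177 higher and 53 lower (244 and 74 as deposited, 358 and 47 after median centring). Its median change was 0.40 units, above the highest of 10000 level-matched random lists of probes (0.10 units). Relative to all kept probes the median RRM change was 0.41 units, and 0.53 in the deposited values. CAS probes changed by a median of -0.12 units relative to all probes, and EXP2 by -0.16. The EXP1 median change of -0.13 units lay below the central 95% of its random lists (-0.090 to 0.0027). For EXP1 the relative median was -0.12 units but 0.0021 in the deposited values, so no direction is given for that median. Of the CAS sets, 164 were higher and 174 lower in the adult, against 238 and 215 as deposited and 370 and 111 after median centring. CAS:2391 was 2.37 ± 0.21 and CAS:2140 2.03 ± 0.15 units higher. CAS:2266 went from 7.17 ± 0.06 to 3.84 ± 0.10, a change of -3.33 ± 0.11, and CAS:2183 changed by -3.20 ± 0.38. Median centring gave 68.7% of the counted probes as higher in the adult, where the median kept probe was 0.25 units higher, against 47.4% after quantile normalization and 48.2% as deposited. The adult column had a wider interquartile range (2.85 units) than the larval columns (2.14 to 2.36), and its deposited median lay 0.21 units below that of L4.

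Across the whole interval, 37731 probes were higher and 38623 lower in the adult than in L1, 46.5% of those kept, and at 2 units 11984 were higher and 9905 lower. RRM probes were mostly higher in the adult, 385 against 95, with a median change of 0.60 units where the highest random list reached 0.21. That median was 1.00 units as deposited and 1.03 after median centring. CAS probes were more often lower, 2718 against 1439 (2191 against 1967 as deposited and 2133 against 2045 after median centring). Their relative median change was -0.35 units, also -0.35 as deposited. CAS:835 was 4.28 ± 0.50 and CAS:840 3.86 ± 0.23 units higher in the adult. CAS:3272 changed by -5.54 ± 0.33 and CAS:3271 by -5.20 ± 0.50, with both near 8.4 units in L1. In total, 310 CAS sets were higher and 608 lower, and at most 2 were counted from spot error alone. This lean of the sets to lower values was absent in the deposited values (455 higher and 451 lower) and after median centring (480 and 451), in which the median of all kept probes was 0.33 and 0.35 units higher in the adult. Deposited values placed 60.8% of the counted probes higher in the adult, and quantile-normalized values 49.4%.

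**Figure D2:**
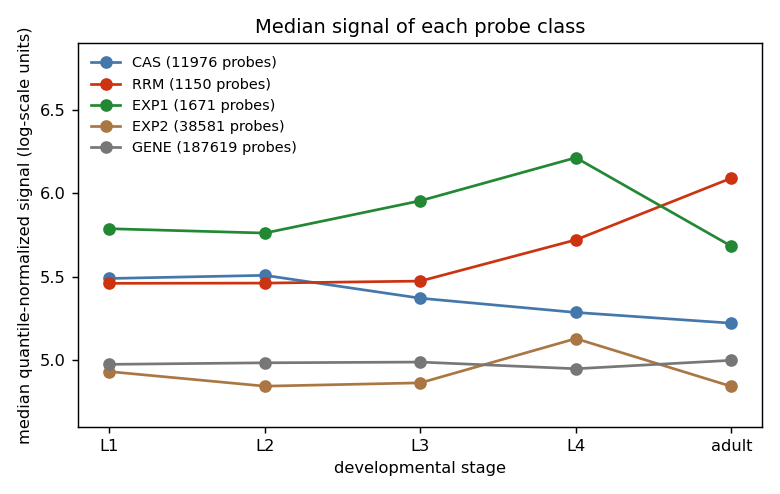
Points give the median quantile-normalized signal (log-scale units, vertical axis, not starting at 0) of all probes of each class at each stage (horizontal axis), with 1 sample per stage and no error bars. The RRM median goes from 5.46 in L1 to 6.09 in the adult, and the EXP1 and EXP2 medians are highest in L4 (6.21 and 5.13). The GENE median stays between 4.95 and 5.00, which quantile normalization largely fixes, since GENE holds 77.9% of the probes. As deposited it ran from 4.90 in the adult to 5.06 in L4.

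Most probes had a range of at least 1 unit over the 5 stages, 117233 of the 164049 kept, or 71.5%. Of these, 31.3% were highest in the adult, 28.9% in L1, 13.8% in L4, 13.1% in L2 and 12.95% in L3. The adult was also the stage of the lowest value for 34.4%, and L1 for 28.7%. The classes differed in this distribution. Among RRM probes 57.9% were highest in the adult and 3.93% in L3. CAS probes were most often highest in L1 (35.4%) and lowest in the adult (44.8%). These class shares are given for the quantile-normalized values alone. From L1 to the adult, CAS probes split nearly evenly after median centring (2045 higher and 2133 lower). L4 held the highest value of 22.99% of EXP1 and 20.6% of EXP2 probes, against 12.7% of GENE and 8.67% of CAS probes. As deposited, 40.5% of the probes were highest in the adult.

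**Figure D3:**
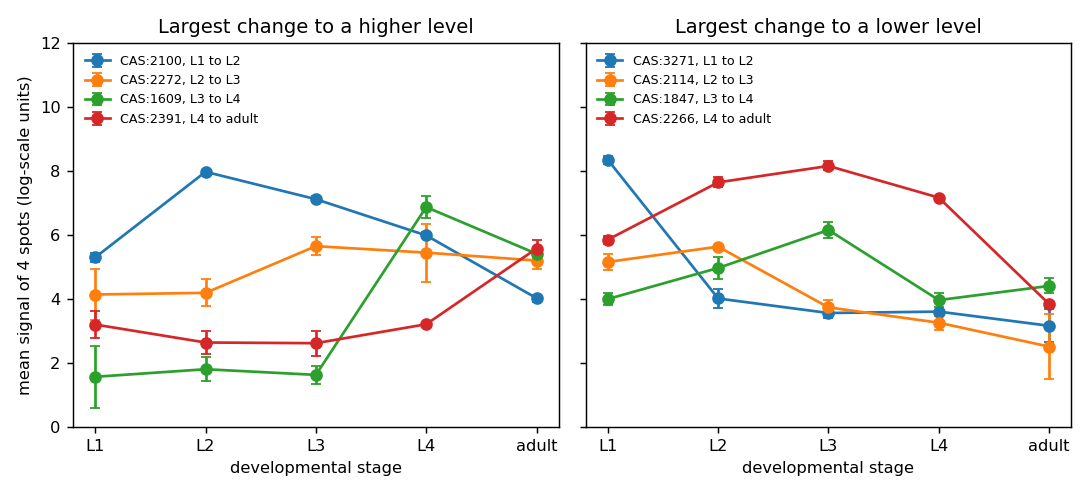
Points give the mean quantile-normalized signal (log-scale units, vertical axis) of the 4 spots of a CAS probe at each stage (horizontal axis), and bars the SD over the spots, for the set with the largest change to a higher (left) or lower (right) level between each pair of adjacent stages. CAS:1609 is at 1.62 in L3 and 6.87 in L4, and CAS:3271 goes from 8.36 in L1 to 4.01 in L2.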

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

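The sign of the median RRM change from L2 to L3, 0.023 units, turned to -0.0065 as deposited and -0.014 after median centring, so no direction is given for that median. The central 95% of its random lists, drawn from the quantile-normalized values, ran from -0.015 to 0.056 units. The RRM medians of the other 4 comparisons kept their sign. With 1 sample per stage, no replicate could be left out, and no paired analysis was possible because each stage has 1 sample. The counts of probes that differ by at least 1 unit stayed within 1.5 times of the reported ones under the deposited values, median centring and the removal of probes at a ceiling. The split by direction moved more in some comparisons, as given there, and median centring gave 61.4% higher from L1 to L2 and 61.7% from L1 to the adult. From L2 to L3 the share higher was 48.6%, with 45.2% as deposited and 43.4% after median centring. In the order L1 to L2, L2 to L3, L3 to L4, L4 to adult and L1 to adult, a 75th percentile filter gave 21413, 5518, 14762, 23207 and 48056 probes, since fewer were eligible, and a threshold of 2 units gave 4573, 270, 5029, 4792 and 21889. A threshold of 0.69 units, which is 2-fold if the scale is a natural log, gave 58640, 27213, 48863 and 65498 for the adjacent pairs. Without a level filter L2 to L3 gave 14468. The median RRM change from L4 to the adult was 0.78 units after median centring, where the median kept probe was 0.25 units higher. The inferred events with an inclusion shift, described under other observations, numbered 37, 20, 28 and 86 without a level filter for L1 to L2, L3 to L4, L4 to adult and L1 to adult, and in the deposited values 1 for L2 to L3 and 27 for L4 to adult; the cause was not tested. Gene lists, a mean over the probes of a gene and a floor for linear values need gene names or a linear scale and were not run. Ceilings in L2 and L4 hide the true level of the brightest probes there, so a rise to such a value is a lower bound and a rise from it an upper one, and without a background measure the lowest levels have no known order.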

Other observations

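The tests of the hybridizations and of the order of the CAS identifiers, and the correlation tests of inclusion shifts other than those from L4 to the adult, were chosen after their results had been seen; those of the RRM class and the other tests of inclusion shifts were written before, although the deposited class means of the RRM probes had been seen by then. The rule that a test stays undecided if its interval spans a limit or, for compression, leaves out 0, and the comparison with the SD of the flanking difference, were added to the correlation tests of inclusion shifts after the results. Of the kept probes, 4.39% were higher at every step through the 5 stages and 6.25% lower at every step, an order that turned in the deposited values (6.78% and 4.82%). Any single order of 5 values would hold 0.833% if all orders were equally frequent. The stages are not interchangeable, since L1 and the adult most often held the highest and the lowest values. A share above 0.833% is therefore no test of steady courses. RRM probes were higher at every step in 9.90% and lower in 1.49%, and CAS probes in 2.16% and 8.23%, with the same directions in the deposited values (13.4% and 0.595%, 3.56% and 5.20%). Probes with neighbouring GENE numbers had like profiles, with a mean similarity (cosine of the centred stage profiles) of 0.594 between adjacent numbers, 0.372 at a distance of 10 and 0.060 at 100. Over all GENE probes, without the level filter, 528 runs of at least 5 consecutive probes were all lower from L4 to the adult by at least 1 unit and 364 runs all higher, where 100 shuffles of the order gave at most 4 and 10. The longest run of lower probes, 60 probes, had a median change of -3.18 units, and the longest of higher probes held 38. From L3 to L4 there were 568 runs of higher and 149 of lower probes, against at most 3 of either after shuffling.

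The adult and L3 columns are described as 3 hybridizations each, but their decimals and spots do not show 3. In the adult column 100% of the values are multiples of 0.00005, as in the other 4 columns, which a mean of 2 numbers with 4 decimals gives and a mean of 3 does not. Spot residuals, the deviations of the 4 spots of a CAS probe from their mean, correlated at r = 0.585 between the adult and L2, 0.532 between L1 and L4 and 0.474 between L1 and L3, stages that shared arrays. Residuals of the adult and L3, which also shared an array, correlated at 0.127, below all 5 pairs that shared none (0.177 to 0.307), and those of L3 and L4, another pair with a shared array, at 0.223. A candidate explanation is that each deposited value averages 1 Cy3 and 1 Cy5 hybridization and that an array was left out for the adult and for L3; unequal weights in an average rounded before deposit stay open.

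The RRM class was higher in the adult than in L4 by 0.403 units in the median. Column spread as the whole cause is argued against by the change relative to all probes, 0.534 units as deposited, of which quantile normalization left 0.408. Median centring moves all probes of a column alike and is no further test. The level of the probes is argued against by the random lists matched on it, none of which passed 0.099. The ceiling of L4 itself is argued against by the number of RRM probes at a ceiling, 10 of the 1010 kept, too few to set the median. The relative change of 0.404 without the probes at a ceiling adds no further test, since removing so few could hardly move it. Compression just below the ceiling was not tested. The adult and L4 shared no array, so a difference between arrays may also contribute, and a difference of the stage itself remains untested with 1 sample per stage.

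Consecutive CAS numbers may hold the probes of 1 cassette event. Blocks of 6 had a mean profile similarity of 0.647 when they began at the first number, and at most 0.466 with any other start, as 499 blocks of 6 would give. In these blocks CAS:2099 and CAS:2100 fall together, as do CAS:3271 and CAS:3272, CAS:1609 and CAS:1612, CAS:1845 and CAS:1847, and CAS:835 and CAS:840. Each of these pairs may thus follow 1 transcript. Within blocks, positions 2, 4 and 5 stood apart from positions 1, 3 and 6. In 68.7% of the blocks (343 of 499), positions 2, 4 and 5 were closer to each other than to the rest. Of the 10 ways to split 6 positions into equal groups, this one had the largest gap between similarity within and between groups, 0.148 against 0.0034 for the next. This split was chosen after the similarities of these same blocks had been seen, so the values describe it and do not test it. The pattern suggests a cassette exon at position 2 with its junctions at 4 and 5, and flanking exons at 1 and 3 with the skipping junction at 6, as a hypothesis on the layout.

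Under that hypothesis, an inclusion shift (mean change of positions 2, 4 and 5 minus the change of position 6) of at least 1 unit, in the same direction on all 4 spots, was found in 19 of 257 events from L1 to L2, 2 from L2 to L3, 11 from L3 to L4, 13 from L4 to the adult and 50 from L1 to the adult. Spot noise alone gave a mean of 0 events from L1 to L2. Differences between the inferred flanking exons 1 and 3, which splicing of the cassette would not move, reached 1 unit in 12, 2, 4, 11 and 29 events, so from L4 to the adult (11 against 13) the shifts cannot be told apart from probes that disagree for other reasons, nor were they more frequent from L2 to L3 (2 against 2). From L4 to the adult the shifts numbered 27 against 12 flanking differences in the deposited values and 28 against 29 without a level filter, so the settings disagree. From L3 to L4 they numbered 10 against 7 and 20 against 15, and from L1 to L2 15 against 8 and 37 against 26. From L2 to L3 they numbered 1 against 2 and 3 against 6, and from L1 to the adult 60 against 21 and 86 against 63. The flanking difference compares single positions, whereas the shift holds a mean of 3, so these are counts of unlike measures. Compression of dim probes stays open from L4 to the adult, where the shift correlated with the flanking exon change at r = -0.189 across events (95% interval -0.305 to -0.069, which reaches past the limit of -0.3). It stays open from L1 to the adult as well, with an r of -0.153 (-0.271 to -0.032). The r was -0.051 from L1 to L2 (-0.172 to 0.072), 0.025 from L2 to L3 (-0.097 to 0.147) and 0.022 from L3 to L4 (-0.101 to 0.144), which argues against a compression that acts on all events in 1 direction in those 3 comparisons; one that acts on the shifted events alone was not tested. Opposite movement of the skipping junction and the cassette exon, measured with no shared probe, gave r = -0.034 from L4 to the adult (95% interval -0.156 to 0.089), -0.085 from L1 to L2, -0.0014 from L2 to L3 and -0.173 from L1 to the adult (-0.290 to -0.052), which do not decide against a limit of -0.1. From L3 to L4 it gave -0.243 (-0.355 to -0.125), past that limit. This does not decide either, since a difference between flanking exons 1 and 3 enters both sides of the measure, and its SD over events (0.482 units) was no smaller than that of the shift (0.471). The largest shift, in the block that starts at number 715, was 3.09 ± 0.36 units (SD, n = 4 spots) from L4 to the adult, with a change of -2.44 units at position 6 and 0.65 at the inclusion positions.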
